A study of Rattus norvegicus with 40 samples.

How the data were processed

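Total RNA from rat cerebral cortex was measured on 40 Affymetrix 1-colour expression arrays, 20 from the group labelled as hypoxic preconditioning and 20 from the group labelled as sham, which was kept in normal oxygen. Per the labels, the samples of each group carry the numbers 1 to 20, and they are listed as 5 preconditioned and then 5 sham samples at a time. This gives 4 number runs, 1 to 5, 6 to 10, 11 to 15 and 16 to 20, with 5 arrays per group in each. The labels used here do not say what the runs are, for example times, litters or processing days, and no condition was assigned to them. Nothing in the labels says that the samples came from separate animals. By their sex transcripts, both sexes occur among the 5 arrays of every group and run, so these did not all come from the same animal. Whether each sample is a separate animal is not given, so the p-values measure only the spread between these samples, which may be technical in part. The oxygen level, the length of the exposure and the age of the rats are not given in the sources used here.

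The deposited values are linear probe set intensity values, 1 per probe set and array. The software and the scaling behind them are not given in the sources used here. In the deposited values themselves, the mean intensity of an array without the lowest and highest 2% of its probe sets lay between 150.04 and 150.06 on all 40 arrays, so each array had been scaled to a common mean. No detection calls were used here. The table held 31099 probe sets, of which 57 were control probe sets and were left out.

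Intensities below 16 were set to 16 and log2 was taken. The medians of the arrays on the log2 scale spanned 0.29, which is under the limit of 0.3 fixed beforehand, so no further normalization was applied. At the floor lay 25.7% of all values. Probe sets whose mean log2 value over all arrays reached the 40th percentile, an intensity of 31.9, were kept, which left 18625 of 31042, and 0.149% of their values lay at the floor. Gene names came from the platform annotation. Of the 31042 probe sets, 20826 had 1 gene, 436 had several and 9780 were unnamed there. Among those kept, 14273 had 1 gene, covering 10304 genes, while 309 had several and 4043 were unnamed. No gene was named from a probe set with several. Of 20832 annotated probe sets with 1 gene, 20764 matched a gene ID in the RefSeq gene table of assembly GRCr8, and 0 symbols needed an update. No genome coordinates are given, because the annotation and that assembly were not shown to share a build. Where a gene had several kept probe sets, the one with the highest mean over all arrays stood for it, and no other kept probe set of a named gene was called in the opposite direction.

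Preconditioned and sham arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend), first over all 40 arrays without covariates and then within each number run as contrasts from 1 fit of 8 group means, which share an estimate of the spread. A moderated F-test of the interaction asked whether the preconditioning effect differed between the runs. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. A difference is written as preconditioned minus sham on the log2 scale with the standard error of the fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 125 pairs of 25 lists and 5 contrasts, again with an estimated correlation, and with fry. The 26 lists covered hypoxia and stress pathways, cell processes and the markers of cortical and neighbouring cell types. The Y chromosome list had 2 measured genes, under the minimum of 4, and was not tested as a list.

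The mean log2 level of each list per array was compared between runs by permuting the group labels within runs 100000 times, with the variance of the 4 differences as the statistic. Because that null mixes the real group differences into the permuted values, a second permutation of the residuals of an additive model of group and run was added after the result of the first had been seen, and both are given.

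The lists, the designs and most alternatives were fixed before the data were examined. So was the rule for the genes named, which took the 10 largest rises and falls over all arrays and the 5 largest in each run among called genes. It added up to 4 called members of each list, the 10 genes with the smallest interaction p, and 12 genes known from hypoxia or stress responses whatever their result. Adm and Mt1a, among these 12, had no kept probe set of their own. On simulated data with the real spread, in which 200 of 18625 probe sets were changed, the fit over all arrays recovered 95% of changes of 0.5 and 100% of changes of 1 on the log2 scale. Within runs the fits recovered 59% to 62% and 94% to 96%, and the interaction test 35% and 89%.

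Alternatives were quantile normalization, median centring, a floor of 1, a pseudocount of 32, no filter or one at the 60th percentile, no mean trend, array weights, the sample number as a block, the number run or the level of Y chromosome genes as a covariate, the 10 arrays of a run alone, and leaving out each array. Leaving out preconditioned arrays 5 and 6 and taking shared genes out of the lists were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.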

Results

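The 40 arrays measured the expression of 10304 named genes in the cerebral cortex of rats after hypoxic preconditioning, a mild exposure to low oxygen used to raise the tolerance of the brain to a later insult, or after a sham exposure in normal oxygen. Each group had 20 arrays, 5 in each of the 4 runs of sample numbers. The number of arrays limits the precision. Ratios of 3' to 5' control probe sets, a sign of RNA integrity, ranged from 1.38 to 1.90 for actin and from 0.892 to 1.06 for GAPDH. Xist, which is transcribed in females, and Eif2s3y, a Y chromosome gene, marked 9 arrays in each group as male. Preconditioned arrays 5 and 6 stood apart, with array medians of 5.59 and 5.53 on the log2 scale, against 5.71 or more on the others, and positions of 35.6 and 34.3 on the second principal component, against -12.7 to 12.2.

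Over all arrays, genes of the response to low oxygen and single genes of blood vessels and astrocytes were higher after preconditioning. Vegfa, the main growth factor of blood vessels, rose by 0.68 ± 0.11 (log2, SE, n = 20 per group, limma adjusted p = 0.00026), or 1.60-fold, and 17 of the 20 preconditioned arrays lay above all sham arrays. Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.68 ± 0.12 (limma adjusted p = 0.002), and Ldha, which makes lactate from pyruvate, by 0.37 ± 0.06 (limma adjusted p = 0.00045). Von Willebrand factor, Vwf, a product of endothelial cells, rose by 0.49 ± 0.07 and had the smallest adjusted p of this comparison (limma, 7.5e-05). Col4a1, a collagen of vascular basement membranes, rose by 0.29 ± 0.04, and Gfap, the intermediate filament of astrocytes, by 0.66 ± 0.14. As lists, the astrocyte markers had 2 of 21 members higher (adjusted p = 0.55 with an estimated correlation, limma's camera) and the endothelial and mural markers 2 of 25 higher and 1 lower (0.38).

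Among the genes that were lower over all arrays, Serpinb6b fell by 0.54 and Apol3l1 by 0.51 on the log2 scale. Slc38a5, a glutamine transporter, fell by 0.30, Spc25, a kinetochore protein, by 0.29, and Slco1c1, a thyroid hormone transporter of the blood-brain barrier, by 0.28. In all, limma called 166 of 18625 probe sets, 113 higher and 53 lower, naming 86 and 43 genes, with 2781 at an unadjusted p under 0.05.

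Of these 166 probe sets, 76 were also called in numbers 1 to 5, 83 in 6 to 10, 8 in 11 to 15 and 0 in 16 to 20. Without numbers 1 to 5 the count was 22 and without 6 to 10 it was 7, while without 11 to 15 it was 192 and without 16 to 20 it was 637 (307 higher, 330 lower). With the number run as a covariate it was 502 (286 higher, 216 lower), and for the average of the 4 run effects 744 (385 higher, 359 lower). With the sample number as a block it was 589 (324 higher, 265 lower). The share of higher genes therefore depends on how the runs and numbers are treated. The call of Slc2a1 ended without numbers 1 to 5 and without 6 to 10 (limma adjusted p = 0.147 and 0.159), that of Ldha without 1 to 5 (0.061), that of Vegfa without 6 to 10 (0.055), and those of Gfap and Slc38a5 without 6 to 10 (0.26 and 0.272) and without 11 to 15 (0.094 and 0.147). In all, 29 calls of named genes ended without 1 to 5, 30 without 6 to 10, 6 without 11 to 15 and 1 without 16 to 20. Median centring gave 153 higher and 41 lower. Without preconditioned arrays 5 and 6, the count was 101, and Fos, Angpt2, Cebpd, Egr1 and Slco1c1 were among the calls that ended, with limma adjusted p of 0.101, 0.072, 0.074, 0.084 and 0.076.

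Of 37 measured HIF targets and glycolytic enzymes, 12 rose over all arrays and 0 fell. Adjusted over the list alone, 25 rose and 1 fell. Beside Vegfa, Slc2a1 and Ldha, these included Angptl4 (0.54 ± 0.10), Ddit4, an inhibitor of mTOR signalling (0.53 ± 0.12), and Bnip3, a mitophagy receptor (0.23 ± 0.05). Of 19 genes of the glucocorticoid response, 4 rose and 0 fell, or 15 and 0 over the list alone, with Sgk1, a kinase, at 0.29 ± 0.07. Of 23 immediate early genes, 2 rose, Fos (0.97 ± 0.25) and Egr1 (0.51 ± 0.12), and of 29 genes of angiogenesis and vessel remodelling 4 rose, among them Plat, tissue plasminogen activator, by 0.47 ± 0.10. With an estimated correlation, the adjusted p of limma's camera was 0.00048 for the HIF list, 0.0022 for the glucocorticoid list, 0.034 for the immediate early genes and 0.014 for angiogenesis. Without preconditioned arrays 5 and 6 it was 0.059 for the immediate early genes, and without genes shared with other lists 0.082 for angiogenesis. The HIF list shared 9 of its 37 genes and the glucocorticoid list 7 of its 19 with other lists.

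Within numbers 1 to 5, the single genes with the largest rises included Fos and several targets of HIF. Fos, a transcription factor induced within minutes of stimulation, rose by 2.62 ± 0.26 (log2, SE, n = 5 per group, limma adjusted p = 2.4e-09), or 6.14-fold. Depp1, a target of FOXO factors, rose by 2.08 ± 0.21, Ddit4 by 1.56 ± 0.08 (limma adjusted p = 4.2e-18), Slc2a1 by 1.46 ± 0.08 and Vegfa by 1.42 ± 0.08. For each of these genes all 5 preconditioned arrays lay above all 5 sham arrays. Genes that fell included Slc40a1, the cellular iron exporter, by 0.94, Serpinb6b by 0.94, Jag1, a Notch ligand, by 0.89 and Slco1c1 by 0.58.

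In this run 23 of 37 members of the HIF list rose and 0 fell, among them Kdm3a, a histone demethylase, by 1.31 ± 0.09 and Egln3, an oxygen-sensing prolyl hydroxylase, by 0.51 ± 0.10. Of 19 glucocorticoid response genes 8 rose, including Cebpd by 1.27 ± 0.19, Sgk1 by 0.62 ± 0.08 and Errfi1 by 0.61 ± 0.09. Of 23 immediate early genes 6 rose, including Egr1 by 1.21 ± 0.16, Zfp36, which destabilises cytokine mRNAs, by 1.11 ± 0.19 and Dusp1, a MAP kinase phosphatase, by 0.81 ± 0.15. Of 29 angiogenesis genes 8 rose and 1 fell. Angpt2, an antagonist of the Tie2 receptor, rose by 1.41 ± 0.18, Apln, the ligand of the apelin receptor, by 1.33 ± 0.12, Flt1, a VEGF receptor, by 1.16 ± 0.23 and Plat by 1.14 ± 0.09. The cell cycle list had 2 members lower among 42, Ccnd1 (cyclin D1) at -0.53 ± 0.11 and Mcm6 at -0.46 ± 0.12. The call of Mcm6 ended when any of 5 arrays was left out, with a limma adjusted p of up to 0.125 without preconditioned array 5.

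For numbers 1 to 5, the adjusted p with an estimated correlation was 7e-10 for the HIF list, 4.4e-10 for the glucocorticoid list, 0.0022 for the immediate early genes and 0.0005 for angiogenesis (limma's camera). Limma called 445 probe sets, 230 higher and 215 lower, against 314 and 130 with median centring and 262 and 149 with quantile normalization. The count was 268 without preconditioned array 5 and 273 without sham array 3, 289 without sham array 4, and 161 when only the 10 arrays of the run were fitted, which ended the call of Egln3 (limma adjusted p = 0.074).

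**Figure D1:**
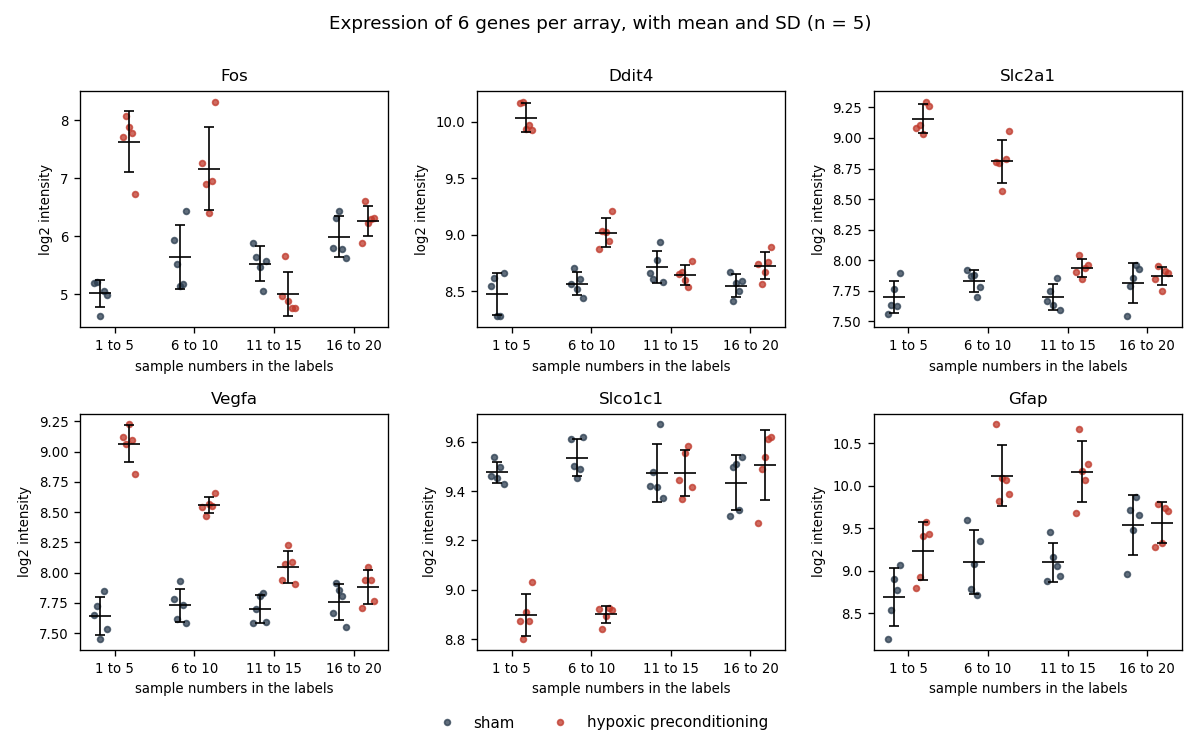
Log2 intensity of Fos, Ddit4, Slc2a1, Vegfa, Slco1c1 and Gfap on each of the 40 arrays (vertical axes) by run of sample numbers (horizontal axes), with sham arrays in dark blue, preconditioned arrays in red, and black bars for the mean and SD of the 5 arrays. In numbers 1 to 5 all preconditioned arrays lie above all sham arrays for Fos, Ddit4, Slc2a1 and Vegfa and below them for Slco1c1, while in 16 to 20 the groups overlap.

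Within numbers 6 to 10, Angpt2 rose by 1.82 ± 0.18 (log2, SE, n = 5 per group, limma adjusted p = 1.3e-08), or 3.53-fold, Fos by 1.52 ± 0.26, Pla1a, a phospholipase, by 1.30 ± 0.19 with 1 sham array at the floor, and Shc4, a signalling adaptor, by 1.04 ± 0.17. Slc2a1 rose by 0.98 ± 0.08, Angptl4 by 0.95 ± 0.13, Apln by 0.90 ± 0.12, Ak4, a mitochondrial adenylate kinase, by 0.89 ± 0.13 and Vegfa by 0.83 ± 0.08. Gfap rose by 1.02 ± 0.19 and Mrc1, the mannose receptor of perivascular macrophages, by 0.74 ± 0.14, while 3 of 21 astrocyte markers were called (adjusted p = 0.60 with an estimated correlation, limma's camera). Serpinb6b fell by 1.05, Slc40a1 by 0.76, Slco1c1 by 0.63, Sdf2l1, an endoplasmic reticulum protein, by 0.55 and Tek, the angiopoietin receptor Tie2, by 0.51.

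Of the 37 HIF list members, 14 rose and 0 fell in numbers 6 to 10. Of 19 glucocorticoid response genes 11 rose, including Errfi1 by 0.53 ± 0.09, Sgk1 by 0.47 ± 0.08 and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.53 ± 0.13. Per1, a clock gene, was also called higher, by an amount that depends on the floor, since 3 of the 5 sham arrays lay at it. Its call ended when any of 5 arrays was left out, with a limma adjusted p of up to 0.099 without sham array 8, and that of Fkbp5 ended when either of 2 arrays was, with up to 0.065 without sham array 10. Of 23 immediate early genes 2 rose, and of 29 angiogenesis genes 6 rose and 1, Tek, fell. With an estimated correlation, the adjusted p of limma's camera was 2e-07 for the HIF list, 2.9e-09 for the glucocorticoid list, 0.0017 for the immediate early genes and 0.013 for angiogenesis, and 0.114 for angiogenesis without genes shared with other lists.

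For numbers 6 to 10 limma called 413 probe sets, 204 higher and 209 lower, against 254 and 154 with median centring. Without preconditioned array 6 the count was 219, without sham array 7 it was 236, without sham array 8 it was 217, without preconditioned arrays 5 and 6 it was 265, and in the 10 arrays of the run alone it was 96. Fitting the run alone ended the calls of Per1, Tek, Fkbp5, Sgk1 and Sdf2l1, with limma adjusted p of 0.109, 0.074, 0.069, 0.052 and 0.051. Between numbers 1 to 5 and 6 to 10, which share no arrays, 87 probe sets were called higher in both and 28 lower in both. Independent lists would give 2.52 and 2.41, and 0 were called in opposite directions. The 2 lists are not fully independent, since the fit shares an estimate of the spread. Preconditioned arrays 5 and 6, which stand apart, also lie 1 in each run. Without them 208 higher and 137 lower were called in 1 to 5, and 158 and 107 in 6 to 10. The overlap was not recomputed without them.

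Within numbers 11 to 15, few genes differed, and Gfap was among them. Pla1a rose by 1.16 ± 0.19 (log2, SE, n = 5 per group, limma adjusted p = 0.0042), with 1 sham array at the floor, and Gfap by 1.07 ± 0.19 (limma adjusted p = 0.0051), or 2.10-fold. Apln, which rose in numbers 1 to 5 and 6 to 10, fell here by 0.68 (limma adjusted p = 0.0042). Slc38a5 fell by 0.61. Vegfa was 0.34 ± 0.08 higher, which did not pass (limma adjusted p = 0.11), although all 5 preconditioned arrays lay above all sham arrays. Of the HIF list 0 members were called, or 7 higher and 2 lower over the list alone. The HIF list as a whole was called by camera at the preset correlation, with an adjusted p of 0.17 with an estimated correlation. Mt2A (0.68 ± 0.14), a metallothionein, Vwf (0.61 ± 0.13), Timp1 (0.61 ± 0.13), a metalloproteinase inhibitor, and Bmper (-0.57 ± 0.12) were also called.

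Limma called 13 probe sets in this run, 9 higher and 4 lower, with 1835 at an unadjusted p under 0.05, against 8 and 6 with median centring. The count was 3 without preconditioned array 12, 5 without sham array 15, 7 without sham array 11 or 13, 8 without preconditioned array 11 and 20 without preconditioned array 13. In the 10 arrays of the run alone it was also 3, and the calls of Pla1a (limma adjusted p = 0.053), Slc38a5 (0.083), Mt2A (0.144), Vwf (0.144), Timp1 (0.177) and Bmper (0.144) ended. It was 22 with quantile normalization and 41 without preconditioned arrays 5 and 6, which lie outside the run. The call of Gfap ended without preconditioned array 12 (limma adjusted p = 0.069), as did that of Slc38a5 (0.071), which also ended without sham array 15, and those of Mt2A, Vwf, Timp1 and Bmper ended when any of 6 or 7 arrays was left out, with adjusted p of up to 0.197, 0.158, 0.197 and 0.13.

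Within numbers 16 to 20, 0 probe sets passed the threshold in limma, with 952 (5.11%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0954. Without the mean trend 1 was called, and without sham array 18 also 1. Here Vegfa was 0.12 ± 0.08, Slc2a1 0.06 ± 0.08, Fos 0.27 ± 0.26, Ddit4 0.18 ± 0.08 and Angpt2 0.10 ± 0.18 higher (log2, SE, n = 5 per group), none past the threshold. At the preset correlation, limma's camera called the cell cycle list lower in this run (adjusted p = 4.6e-06) and also the oxidative phosphorylation list (0.036). With an estimated correlation these were 0.297 and 0.76, and with the sample number as a block as well 0.00021 and 0.73. The mean level of the cell cycle list differed by -0.17, against -0.19 in 1 to 5, -0.17 in 6 to 10 and -0.02 in 11 to 15. In simulations with 200 probe sets changed together, 59% of changes of 0.5 and 94% of changes of 1 were recovered at this size. The adjustment is stricter where fewer probe sets change, and recovery of fewer changes was not simulated. These rates therefore do not show how many isolated changes could be missed in this run.

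The size of the preconditioning effect differed between the number runs for single genes. Ddit4 (limma adjusted interaction p = 5.1e-13), Slc2a1 (5.7e-12), Apln (4e-11), Kdm3a (3.5e-10) and Vegfa (1e-09) had the smallest p, followed by Plat, Slco1c1, Angpt2, Fos and Slc40a1. The log2 difference of Ddit4 went from 1.56 in numbers 1 to 5 and 0.45 in 6 to 10 to -0.07 in 11 to 15 and 0.18 in 16 to 20. Slco1c1 was -0.58, -0.63, 0.00 and 0.07 in the same order. Gfap, at 0.53, 1.02, 1.07 and 0.03, did not pass the test of a difference between runs (limma adjusted interaction p = 0.079), nor did Vwf (0.77) or Col4a1 (0.85). In simulations with the change in numbers 1 to 5 alone, this test recovered 35% of changes of 0.5 and 89% of changes of 1. Differences near 0.5 can therefore be missed. A pattern over several runs such as that of Gfap was not simulated.

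The interaction test called 142 of 18625 probe sets, covering 102 genes, of which 121 were also called in numbers 1 to 5 or 6 to 10. Without preconditioned arrays 5 and 6 it called 187. For the lists, the mean level of the immediate early genes was 0.35 and 0.28 higher after preconditioning in the first pair of runs and -0.01 and -0.05 different in the later ones, a difference between runs that passed the permutation of group labels (adjusted p = 0.0356). The markers of striatum, hippocampus and thalamus also passed (0.08, 0.08, -0.02 and -0.06, adjusted permutation p = 0.0356). The HIF list, with differences of 0.51, 0.32, 0.07 and 0.01, did not (adjusted permutation p = 0.0719), nor did the glucocorticoid list (0.57, 0.47, 0.07 and 0.04, adjusted permutation p = 0.0719) or angiogenesis (adjusted permutation p = 0.0855), and the endothelial and mural markers had 0.439. The residual permutation, added later, keeps the real group differences out of the null, and 6 of the 25 lists passed it. Its adjusted p was 8.3e-05 for the HIF, glucocorticoid and immediate early lists and 0.00019 for angiogenesis. For the markers of striatum, hippocampus and thalamus it was 0.019, and for the heat shock proteins 0.023.

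**Figure D2:**
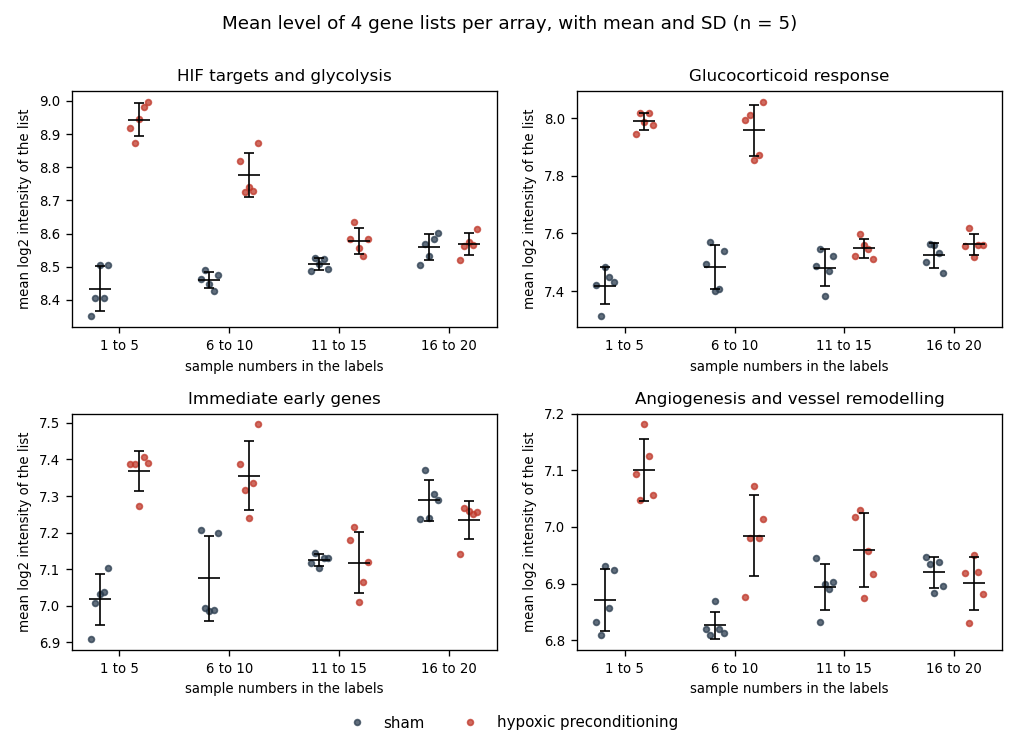
Mean log2 intensity of the members of 4 gene lists on each of the 40 arrays (vertical axes) by run of sample numbers (horizontal axes), with sham arrays in dark blue, preconditioned arrays in red, and black bars for the mean and SD of the 5 arrays. The differences of the HIF list are 0.51, 0.32, 0.07 and 0.01 from the first run to the last.

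Over all arrays, the genes of protein translation lay 0.09 higher at the median, with 0 of 27 called, and those of the cell cycle 0.15 lower, with 0 of 42 called. Both lists were called by camera at the preset correlation, with adjusted p of 0.38 and 0.37 with an estimated correlation. With the sample number as a block as well, these were 0.36 for translation and 0.0096 for the cell cycle. Limma's camera at the preset correlation called 39 of the 125 pairs of list and contrast, and 12 held with an estimated correlation. These were the HIF, glucocorticoid, immediate early and angiogenesis lists over all arrays and in numbers 1 to 5 and 6 to 10. With the block added, the immediate early genes over all arrays were lost (0.078). The cell cycle list then passed over all arrays, in 1 to 5 (0.0025), 6 to 10 (0.017) and 16 to 20 (0.00021). The synapse list passed over all arrays (0.028) and the neuron markers in 1 to 5 (0.024). Without the block, camera called another 11 lists only at the preset correlation, where the smallest adjusted p with an estimated correlation was 0.0763. These were translation, cell cycle, inflammation, astrocyte, neuron and synapse genes, heat shock proteins, the circadian clock, oxidative phosphorylation, cholesterol synthesis and the markers of striatum, hippocampus and thalamus. Fry, which does not compare a list with other genes, passed some of these 11. Among them were the cell cycle, lower over all arrays (fry adjusted p = 0.032), and inflammation over all arrays (0.028) and in 1 to 5 (0.041). Others were the heat shock proteins in 6 to 10 (0.012) and, in 1 to 5, the neuron and the striatum, hippocampus and thalamus markers (0.032 each). The other 10 lists were called by camera in no contrast, with a smallest adjusted p of 0.0685. They were the markers of endothelium, microglia, myelin, meninges, blood cells and choroid plexus. They also included the unfolded protein response, antioxidant response, cell death and growth factors. Camera tests a shift in 1 direction, so opposite changes can cancel. Fry's mixed test, which counts changes either way, gave the endothelial and mural markers an adjusted p of 2e-05 over all arrays. In numbers 1 to 5 it gave 1e-34 (5 members higher, 1 lower) and in 6 to 10 1.1e-32 (3 and 3). In 1 to 5 it also passed growth factors (4.8e-05), the unfolded protein response (3.2e-05) and cell death (0.00093), but not microglia (0.9) or myelin (0.42). The mean level of the 2 measured Y chromosome genes served as a covariate in an alternative fit, and Eif2s3y, with Xist, told the sexes apart. A probe set named for Uty was 0.35 higher in females (log2), so it does not mark the males.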

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

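The tests of array sensitivity and RNA degradation, the residual permutation and the leaving out of preconditioned arrays 5 and 6 were chosen after the results they bear on had been seen.

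The effect of preconditioning differed between the runs of sample numbers for 142 probe sets by limma's interaction test, among them those of Ddit4, Slc2a1, Vegfa and Slco1c1. When the group labels were reassigned within runs, 2 of 100 assignments, the real one included, called as many. A random assignment of the groups within runs can therefore be excluded at the 0.05 level, although the highest other called 166. As for the lists, this null mixes the real group differences into the reassigned values. No null that keeps them out was run for the probe sets. Lower sensitivity of the arrays with later numbers could shrink every difference, but over 11 probe sets that differ by sex and never lie at the floor, the mean sex difference was 1.02 times as large in numbers 11 to 20 as in 1 to 10 (95% interval 0.831 to 1.21), while Vegfa, Slc2a1 and Ddit4 lost most of theirs. This test replaced one on Xist, whose level in males is set by the floor. The 2 arrays that stand apart are not the source either, since 187 probe sets were called without them. What stays open is what the runs are, because the labels do not say whether they are times after exposure, litters or processing days; no biological explanation was tested.

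The mean level of the immediate early genes and that of the markers of striatum, hippocampus and thalamus also differed in their preconditioning effect between runs, each with an adjusted permutation p of 0.03562. The residual permutation called 6 lists, including the HIF and glucocorticoid lists, so how many lists differ depends on the null that is used.

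Preconditioned arrays 5 and 6 had median log2 values of 5.586 and 5.525, far below the other 4 preconditioned arrays of their runs. Degraded RNA is not supported, since 0 of their 6 ratios of 3' to 5' control probe sets lay above those of all other arrays. A difference in brightness or contrast could contribute, as both arrays hold the 2 lowest medians and quantile normalization removed 30.5% of their distance on the second component, which neither reaches the level set for that cause nor excludes it. Whether these samples responded more strongly to hypoxia stays open too. The HIF list level of array 5 lay above each of the other 4 preconditioned arrays of its run, while that of array 6 lay 0.731 SD above their mean but below the highest of them.

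The array median and the levels of gene lists were examined in each set of 5 arrays of a group and run, in 40 tests. In 5 tests an array's gap to its neighbour exceeded 0.71 of the set's range, where chance gives about 2. The tests use the same arrays and are not independent. Besides those above, the immediate early genes were low on preconditioned array 3 (mean log2 level 7.271) and on preconditioned array 16 (7.142). The angiogenesis list was high on sham array 8 (6.869).

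Other splits of the arrays bear on each count of calls. Over all arrays, 1 of 100 splits, the real one, reached 166, and the highest other called 1, so chance can be excluded. The same held for numbers 1 to 5 (1 of 100, real 445, highest other 13), for 6 to 10 (1 of 100, real 413, highest other 154) and for 11 to 15 (1 of 100, real 13, highest other 2). For numbers 16 to 20 the real count was 0, which all 100 splits reach by construction, so the splits decide nothing there; the highest other called 6.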

How the results depend on the processing

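Leaving out preconditioned arrays 5 and 6, the residual permutation and taking shared genes out of lists were added after the data had been seen. Across all alternatives, 3089 of the values of named genes stayed on the same side of the threshold, 277 no longer passed and 24 newly passed. Among values called in either fit, 0 reversed direction. The 3089 include values called in neither fit, for which a change of direction was not counted. For called lists, 262 stayed called in the same direction, 60 no longer passed and 1 reversed. Only lists called in the main test were followed, so none could newly pass. The cause was not tested except where the number of arrays or probe sets changed by construction. The array-based signal limits calls among dim probe sets, which the filter removes.

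Over all arrays (166 calls), the count was 89 without a filter, 264 with array weights, 502 with the number run as a covariate, 744 for the average of the 4 run effects, 101 without preconditioned arrays 5 and 6, 22 without numbers 1 to 5, 7 without 6 to 10 and 637 without 16 to 20. Numbers 11 to 15 (13 calls) gave 22 with quantile normalization, 22 with a filter at the 60th percentile and 41 without arrays 5 and 6, while 6 to 10 (413) gave 265 without them. Fitting only the 10 arrays of a run gave 161 in 1 to 5, 96 in 6 to 10 and 3 in 11 to 15. Numbers 16 to 20 (0) gave 1 without the mean trend. The interaction (142) gave 250 with array weights. Of 39 list calls, 12 held with an estimated correlation. The lists that differed between runs went from 2 to 6 with the residual permutation. The oxidative phosphorylation list in numbers 1 to 5 turned from higher to lower with quantile normalization, at an adjusted p of 0.914.

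Leaving out 1 array gave 268 to 436 calls in numbers 1 to 5, 217 to 584 in 6 to 10, 3 to 20 in 11 to 15 and 0 to 1 in 16 to 20.

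The sample number as a replicate block gave 589 calls over all arrays, 677 in 6 to 10, 34 in 11 to 15, 538 in 1 to 5, 0 in 16 to 20 and 184 for the interaction. With this block and an estimated correlation, the cell cycle list was called over all arrays (adjusted p = 0.0096), in 1 to 5 (0.0025), 6 to 10 (0.017) and 16 to 20 (0.00021), the synapse list over all arrays (0.028) and the neuron markers in 1 to 5 (0.024), while the immediate early genes were not called over all arrays (0.078); the other 11 calls held. The main fits had no block, because no label says that the numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at 0.0829 to 0.38, over 0.1 in 18 of 20 pairs. Deviations from the means of group and run correlated above 0 in 20 of 20 pairs. Their mean was 0.153, against -0.0382 for other numbers of the same run. Within runs, 19 of 20 preconditioned and 17 of 20 sham arrays correlated best with their own number, and 20 of 20 pairs matched in sex. These values point to samples paired by number, a hint from the data and not from the design. The unblocked counts may therefore leave out a real pairing.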

Other observations

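The test of the sex match, and the genes named in the comparison of sham arrays, were chosen after their values had been seen.

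Sham arrays also differed between the runs. Between numbers 16 to 20 and 1 to 5, limma called 3419 probe sets, 1602 higher and 1817 lower in 16 to 20. Mbp, a myelin protein, was 1.15 ± 0.23 higher (log2, SE, n = 5 per run, limma adjusted p = 0.0014), Gfap 0.84 ± 0.17, the glutamate transporter Slc1a2 0.77 ± 0.21 and the heavy neurofilament Nefh 0.67 ± 0.17. Sox11 and Dcx, markers of immature neurons, fell by 0.80 and 0.63, and Mki67, Top2a and Mcm4, genes of dividing cells, by 0.48, 0.38 and 0.49. Of 21 astrocyte markers 14 were higher, of 16 microglial markers 10, of 45 synapse genes 17 with 2 lower, of 42 oxidative phosphorylation genes 20 and of 17 myelin genes 5, while 8 of 42 cell cycle genes were lower. With an estimated correlation, the adjusted p of limma's camera was 0.306 for the astrocyte, microglial, synapse, oxidative phosphorylation and myelin lists and 0.459 for the cell cycle. No list passed this test in any comparison of sham runs, where the smallest adjusted p was 0.209. The 0.306 is a value that the adjustment ties between lists. At the preset correlation the adjusted p of camera was 4.3e-10 for oxidative phosphorylation, 1.2e-08 for astrocyte, 7.3e-05 for microglial and synapse, 0.00038 for myelin and 0.001 for cell cycle genes. Of 32 genes of the unfolded protein and amino acid response, 1 was higher and 10 were lower (0.011, or 0.306 with an estimated correlation).

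The sham level of some genes of the preconditioning response moved as well. In sham arrays, 7 of 23 immediate early genes were higher in numbers 16 to 20 than in 1 to 5. Another 2, Nr4a2 and Nr4a3, were lower. Of 37 members of the HIF list 8 were higher and 0 lower. With an estimated correlation, the adjusted p of limma's camera was 0.306 for both lists. At the preset correlation it was 0.017 for the immediate early genes and 0.0025 for the HIF list. Fos was 0.98 ± 0.22 and Egr1 1.00 ± 0.14 higher (limma adjusted p = 0.0035 and 8e-05), so the baseline of the group difference differs between runs. Beside these differences, 421 probe sets were called between numbers 6 to 10 and 1 to 5 in sham arrays and 246 between 11 to 15 and 1 to 5.

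As a hypothesis, the runs may follow the age of the rats, since myelin and astrocyte genes rise and genes of dividing cells and immature neurons fall as the cortex matures. The test set beforehand was that the myelin list rises and the cell cycle list falls past the threshold with an estimated correlation. It gave an adjusted p of 0.306 for myelin and 0.459 for the cell cycle (limma's camera). At the preset correlation, which that test did not use, myelin was higher (0.00038) and the cell cycle lower (0.001). With an estimated correlation, even the oxidative phosphorylation list, with 20 of 42 members higher and 0 lower, stood at 0.306. The test could hardly pass for any list here, so it neither bears the hypothesis out nor excludes it. A processing batch stays open too, because no label separates them. Of 100 assignments of the 20 sham arrays to runs only the real one, 1 of 100, reached the 3332 calls of the F-test over the 4 runs, and the highest other called 2, so chance can be excluded.

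Arrays with the same number in the 2 groups matched in sex by their Xist and Eif2s3y levels in 20 of 20 pairs, while random pairings within runs matched as many with a permutation p of 0.00015.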
